A study of Mus musculus with 22 samples.

How the data were processed

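RNA was measured in medullary epithelial cells (MECs) of the mouse thymus, the cells in which the transcriptional regulator Aire induces many genes of peripheral tissues. Per the labels, live MECs were sorted as CD45-negative cells with low Ly51 and high MHC class II. Thymocytes and other leukocytes carry CD45, so the gate would remove them. Total RNA was extracted with Trizol, amplified and biotin-labelled with a whole-transcript kit, and hybridised to Affymetrix whole-transcript gene arrays. The 22 arrays fall into 8 groups by title, from 2 genotypes, wild type (WT) and Aire knockout (KO), and 4 treatments, DMSO (vehicle), Etopo, Topo and both drugs together (EtopoTopo). Etopo and Topo are abbreviations commonly used for etoposide, an inhibitor of type II topoisomerases, and topotecan, an inhibitor of topoisomerase I. The labels do not spell them out, and doses and treatment times were not used here. Replicate numbers came from the titles. Nothing in the labels says whether an array is 1 mouse or a pool, so p-values measure the spread between these arrays, which may in part be technical.

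The deposited values are probe intensities on a linear scale, and RMA and Affymetrix Power Tools are named in the submitters' processing notes, without versions. The planned design had assumed values on the log2 scale. Because the deposited intensity values were linear, log2 was taken before every test, without a pseudocount, and no other normalization was applied. Array signal gives no depth in counts, and the number of arrays per group (2 or 3) limits the precision.

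Probes were named through the platform annotation. Of 24922 probes, 21425 had 1 gene symbol, 1399 had several and 2098 had none here, and the last 2 kinds were left out. Symbols were checked through Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6, which held 21347 of the probes' identifiers, and 0 symbols changed. Where a symbol had several probes, the probe with the highest mean over all arrays was kept, which left 19752 genes. Disagreement between probes of 1 gene was not examined.

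Differences were tested in R 4.3.3 with limma 3.58.1 (with data.table, version 1.17.8), by lmFit with 1 mean per group over all 22 arrays and eBayes (14 residual and 7.22 prior degrees of freedom). Each contrast was adjusted by the Benjamini-Hochberg method over all genes, and a gene was called changed at an adjusted p under 0.05. The contrasts were KO against WT under DMSO, each drug against DMSO within each genotype, the difference between genotypes of each drug effect (interaction, KO effect minus WT effect), WT Topo against WT Etopo, and WT EtopoTopo against WT Topo. Changes are given on the log2 scale with the standard error (SE) of the fit. Genes were named by a rule. For each contrast between groups, up to 10 called genes with the highest and 10 with the lowest log2 change were eligible if all arrays of one group lay above all arrays of the other. For 3 arrays against 3, chance alone gives such a separation to 10% of genes. For interactions, up to 5 genes each way were eligible, with no criterion on overlap. Sex-linked check genes and predicted, clone-named or small RNA genes were not named. Aire, Top1, Top2a, Top2b and the 4 members of each gene list with the largest change could be named as well.

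Gene lists were tested with camera (limma) at a preset correlation of 0.01 between genes and again with an estimated correlation, each adjusted over the 19 lists of a contrast, and with fry (limma), which asks whether a list's genes on balance move one way. Of 444 members asked for, 397 were measured. The lists held Aire-dependent antigens, Aire-independent antigens, mature MEC, immature MEC, post-Aire cornified MEC, tuft-like thymic epithelium, cortical thymic epithelium (cTEC), thymocyte, B cell, macrophage and dendritic cell, stroma and endothelium, p53 targets, mitosis, DNA replication, core histones, interferon response, NF-kB and cytokine response, immediate early and stress, and Aire partners and topoisomerases. A list is said to have risen or fallen when camera with the preset correlation gave an adjusted p under 0.05, and the value with the estimated correlation is given beside it. Counts of members are given over all genes and adjusted over the list alone. The mean of each list was also taken per array and compared between groups with a two-sided exact permutation test. With 3 arrays against 3, or 2 against 3, that test cannot give a p below 0.1.

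An Aire-induced list of 640 genes held those lower in KO than in WT under DMSO at an adjusted p under 0.05 and at least 2-fold, and an Aire-repressed list of 136 genes held those higher by the same rule. The shift of a list was tested with fry and with camera at an estimated correlation, and each p was adjusted over the 9 tests of that list (3 drug treatments in WT, in KO and between them). This adjustment was added after the data were seen and ended no fry call of the Aire-induced list, and the unadjusted fry p decided whether a call held when an alternative was tried. Both lists were chosen on the DMSO arrays against which the drug effects are measured, so chance alone moves them. Unchanged groups were therefore simulated 100 times against the same DMSO arrays, and the shift was repeated on a list chosen from KO against WT in the arrays of the other two drug treatments. The DMSO arrays of a genotype number 3 and could not be split with 2 in each part, so the list was also chosen with 2 of them and its shift measured against the third, in rotation. Gene length was the span of a gene in the RefSeq table, available for 99.6% of genes.

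The groups, contrasts, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives were a replicate block, leaving out genes with a mean under 7 in every group, quantile normalization, array weights, an intensity trend with robust variances, age or sex as a covariate, only the groups compared, leaving out both WT EtopoTopo arrays of conflicting label, a 2-fold minimum, other lists of Aire-induced genes, and leaving out each array in turn. Leaving out arrays in doubt, a thymocyte covariate, a list chosen on separate DMSO arrays, an exact sign-flip test within replicate pairs and gene length correlations without each DMSO array were added after seeing the data. Leaving out both WT EtopoTopo arrays of conflicting label leaves a single array in that group, so calls lost there do not show a dependence on the labels. The array weights stopped before convergence. The weights gave both KO EtopoTopo arrays 0.2008 and WT DMSO 3 6.497, so counts under that setting are given with this warning.

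The fit was tested on simulated data with 67 or 66 genes changed at each fold. For WT Topo it recovered 44.8% of genes changed 1.5-fold, 94.0% of those changed 2-fold and 100% of those changed 4-fold, with 3 false calls. For KO Etopo, with 2 drug arrays, the shares were 38.8%, 89.6% and 100% with 7 false calls, and for the Topo interaction 11.9%, 67.2% and 100% with 5 false calls. For KO against WT under DMSO they were 41.8%, 100% and 100% with 3 false calls.

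Whether shared replicate numbers pair the arrays was checked by correlating deviations from the group means across genes. The numbers paired the arrays for WT Etopo with WT DMSO (r from 0.335 to 0.592, the highest r of both arrays in 3 of 3 pairs). For KO Topo with KO DMSO r was positive (0.167 to 0.412) but the highest in only 1 of 3 pairs, so pairing there is in doubt. With the replicate number as a block, these comparisons called 1 and 208 genes. In the other contrasts between groups the numbers did not pair the arrays.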

Results

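Gene expression was measured on 22 arrays of sorted MECs from WT and Aire KO mice treated with DMSO, Etopo, Topo or both drugs. There were 3 arrays per group, except KO Etopo and KO EtopoTopo with 2 each. Median intensity was 236.15 to 263.57 per array, and the correlation between replicate arrays was 0.963 to 0.997. The range from the 10th to the 90th percentile of log2 values ran from 3.89 in KO EtopoTopo 1 to 5.01, and it was 4.32 in WT EtopoTopo 2, 4.33 in WT EtopoTopo 3 and 4.42 in KO Topo 1. Transcripts of thymocytes, the developing T cells of the thymus, stood out on 1 DMSO array of each genotype. The mean log2 value of the thymocyte list was 8.36 in WT DMSO 1 and 8.79 in KO DMSO 1, against 7.04 to 7.59 on the other 20 arrays. By label, WT DMSO 3, WT Etopo 3 and all 5 EtopoTopo arrays came from mice of 4 weeks and the other arrays from mice of 6 weeks. The titles of WT EtopoTopo 1 and 2 give both drugs, while their treatment label gives Etopo only. Their mitosis list means (7.61 and 7.85) lay near WT EtopoTopo 3 (7.95) and below WT Etopo (8.42 to 8.53). Their tuft-like list means (10.30 and 10.16) lay near WT EtopoTopo 3 (10.11) and above WT Etopo (9.60 to 9.81). On these lists the values argue against Etopo alone.

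The Aire probe averages over the transcript and does not test the deletion. Mean log2 intensity of Aire was 12.31 (SD 0.11) in WT DMSO, 12.19 (SD 0.13) in WT Etopo, 11.79 (SD 0.21) in WT Topo and 11.68 (SD 0.38) in WT EtopoTopo. In KO arrays it was 12.91 (SD 0.04) under DMSO, 12.89 (SD 0.08) under Etopo, 12.37 (SD 0.53) under Topo and 12.02 (SD 0.84) under EtopoTopo. The change of Aire was -0.53 ± 0.25 in WT Topo (limma adjusted p = 0.414) and -0.63 ± 0.25 in WT EtopoTopo (adjusted p = 0.105), and in KO EtopoTopo Aire fell by 0.89 ± 0.28 (adjusted p = 0.0291). That fall rests on KO EtopoTopo 1, the array of narrowest range, at 11.43, against 12.61 in KO EtopoTopo 2. Xist, the transcript of the inactive X chromosome, was high (11.39 to 12.57), and the Y-linked genes Eif2s3y, Kdm5d and Uty were low on 22 of 22 arrays. These transcripts are those of females, while WT DMSO 1, WT Etopo 2 and WT Topo 2 carry a male label.

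Loss of Aire lowered transcripts of many peripheral tissues in MECs under DMSO (n = 3 per genotype). Mucl2, a mucin-like gene of secretory glands, fell by 6.44 ± 0.20 log2 units (limma adjusted p = 1.74e-15), and Ly6g, a surface antigen of neutrophils, by 5.56 ± 0.17 (adjusted p = 1.41e-15). Transcripts of the neuropeptide precursor Tac2 (-4.88 ± 0.20), the mast cell protease Mcpt2 (-4.59 ± 0.28), the enamel protein Amtn (-4.23 ± 0.23) and parathyroid hormone Pth (-4.19 ± 0.25) fell as well. Of 33 Aire-dependent antigens, 28 fell and 0 rose (28 and 0 adjusted over the list alone), with a median of -1.69 (camera adjusted p = 1.87e-29, and 0.00355 with an estimated correlation). Among them were the milk protein Csn1s2a (-3.93 ± 0.21), the liver cytochrome Cyp1a2 (-3.90 ± 0.18) and Crabp1 (-3.83 ± 0.15). Of these 33 antigens, 22 also belong to the 640 Aire-induced genes.

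Higher in KO were Ctla4, an inhibitory receptor of T cells (2.96 ± 0.17, limma adjusted p = 2.97e-11), the cytokine Il4 (1.92 ± 0.18, adjusted p = 4.01e-08), monoamine oxidase Maoa (1.85 ± 0.19, adjusted p = 2.46e-07) and the cannabinoid receptor Cnr2 (1.84 ± 0.28, adjusted p = 4.5e-05). In total 1462 genes rose and 2363 fell, of which 136 rose and 640 fell at least 2-fold. No single array moved the count of 3825 by more than 1.5-fold.

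Genes of cornified post-Aire MECs fell in the KO (median -0.69, 11 of 17 members fell, also adjusted over the list alone, camera adjusted p = 6.3e-06, and 0.193 with an estimated correlation). They included Klk5 (-2.55 ± 0.18) and the keratins of differentiated epidermis Krt1 (-1.93 ± 0.22) and Krt10 (-1.46 ± 0.19). Interferon response genes also fell (median -0.58, 15 of 26 members fell and 0 rose, 18 and 1 adjusted over the list alone, camera adjusted p = 7.75e-07, and 0.193 with an estimated correlation), with Ifit3 at -2.09 ± 0.26 and Rsad2 at -1.49 ± 0.25. The mature MEC list rose (median 0.25, 5 members rose and 2 fell, 7 and 2 adjusted over the list alone, camera adjusted p = 0.0437, and 0.819 with an estimated correlation). Within it the chemokines Ccl17 (-1.31 ± 0.26) and Ccl22 (-1.23 ± 0.22) fell and the maturation marker Cd83 (0.95 ± 0.15) rose. Aire partners and topoisomerases rose (median 0.16, 5 of 32 members, 3 adjusted over the list alone, camera adjusted p = 0.00795, and 0.819 with an estimated correlation), with Dnmt3l at 1.84 ± 0.18.

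The other 14 lists did not pass between the genotypes under DMSO. Among lists of epithelium and neighbouring cells, medians were -0.31 for Aire-independent antigens (camera adjusted p = 0.488), -0.06 for immature MEC (0.607), 0.08 for tuft-like epithelium (0.79), -0.19 for cTEC (0.885) and -0.08 for stroma and endothelium (0.974). Thymocyte (0.18, adjusted p = 0.447), B cell (-0.19, 0.27) and macrophage and dendritic cell genes (-0.27, 0.256) did not pass either, although the macrophage gene Adgre1 fell by 1.61 ± 0.20. For programs of division and stress, medians were -0.12 for mitosis (camera adjusted p = 0.808), 0.14 for DNA replication (0.0759), 0.09 for core histones (0.607), 0.09 for p53 targets (0.274), -0.02 for NF-kB and cytokine response (0.928) and 0.24 for immediate early and stress genes (0.0561).

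Etopo in WT MECs moved genes little, with Naaladl2 the 1 gene called (1.20 ± 0.17, limma adjusted p = 0.00767, n = 3 per group). At an unadjusted p under 0.05 lay 1097 genes, against 988 expected with no change. Genes of tuft cells, chemosensory epithelial cells that use taste signalling proteins, rose as a list (median 0.55, camera adjusted p = 3.99e-17, and 0.0837 with an estimated correlation). None of its 13 members was called over all genes and 6 rose adjusted over the list alone, with the tuft cell channel Trpm5 at 0.79 ± 0.24 (adjusted p = 0.448). Its mean per array was 9.60 to 9.81 under Etopo and 9.08 to 9.27 under DMSO (exact permutation p = 0.1). The thymocyte list fell (median -0.55, camera adjusted p = 9.85e-08, and 0.33 with an estimated correlation), though 0 of its 17 members were called over all genes or over the list alone, with WT DMSO 1 at 8.36 among the controls. The core histone list rose (median 0.28, camera adjusted p = 2.22e-06, and 0.304 with an estimated correlation), also with 0 of 15 members called either way and with array means that overlapped (exact permutation p = 0.3). Cornified MEC genes (median 0.10, camera adjusted p = 0.00992) and p53 targets (0.02, adjusted p = 0.0151) passed upward, and NF-kB and cytokine response (-0.21, adjusted p = 0.00388) and macrophage and dendritic cell genes (-0.20, adjusted p = 0.0134) downward. With an estimated correlation these adjusted p were 0.382, 0.33, 0.33 and 0.382, and over all genes 0 of their members were called. The p53 median reversed to -0.02 without WT DMSO 3. The count of genes called was 0 without WT DMSO 1, WT Etopo 2 or WT Etopo 3 and 3 without WT DMSO 2.

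Topo in WT MECs raised genes of tuft cells, with single taste genes, and lowered genes of mitosis. The bitter taste receptor Tas2r108 rose by 1.45 ± 0.23 (limma adjusted p = 0.00218, n = 3 per group), the taste G protein Gnat3 by 1.35 ± 0.22 (adjusted p = 0.00244) and Rgs13 by 1.37 ± 0.19 (adjusted p = 0.00136). Of 13 tuft-like genes, 7 rose (11 adjusted over the list alone), among them Trpm5 (1.09 ± 0.24) and the leukotriene synthesis gene Alox5ap (1.02 ± 0.14). The median was 0.72 (camera adjusted p = 5.24e-17, and 0.0753 with an estimated correlation), and the 3 Topo arrays lay above the 3 DMSO arrays (9.78 to 10.07 against 9.08 to 9.27, exact permutation p = 0.1). Of 29 mitosis genes, 6 fell (25 adjusted over the list alone), among them Ccnb2 (-0.84 ± 0.22) and the kinesin Cenpe (-0.79 ± 0.16). The median was -0.56 (camera adjusted p = 1.45e-22, and 0.0753 with an estimated correlation), with 7.85 to 8.15 per array against 8.50 to 8.65 (exact permutation p = 0.1).

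Tissue antigens fell in WT Topo. The stomach pepsinogen gene Pgc fell by 1.16 ± 0.16 (limma adjusted p = 0.00136), Gatm by 1.39 ± 0.21 (adjusted p = 0.00162), Amtn by 1.31 ± 0.23 (adjusted p = 0.00343) and the basement membrane gene Nid1 by 1.28 ± 0.13 (adjusted p = 5.01e-05). Of 33 Aire-dependent antigens 6 fell and 0 rose (10 and 3 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 2.41e-07, and 0.198 with an estimated correlation). The mature MEC list, of the cells that express Aire, also fell (median -0.03, 1 of 23, 3 adjusted over the list alone, camera adjusted p = 0.0257, and 0.522 with an estimated correlation), with Cd40 at -0.72 ± 0.12 and a median of 0.0050 without WT DMSO 1. DNA replication (median -0.11), interferon response (-0.15), NF-kB and cytokine response (-0.20) and B cell genes (-0.15) passed downward with 0 members called (camera adjusted p = 0.00367, 0.00474, 0.0048 and 0.0495, and 0.328, 0.328, 0.328 and 0.285 with an estimated correlation). For their array means the exact permutation p was 0.4, 0.2, 0.2 and 0.1, and only those of B cell genes did not overlap. Cornified MEC genes rose (median 0.36, 2 of 17 members rose, 8 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.00367, and 0.328 with an estimated correlation), with Spink5 at 0.83 ± 0.22. P53 targets rose (median 0.12, 1 rose and 1 fell, 4 and 2 adjusted over the list alone, camera adjusted p = 0.0495, and 0.328 with an estimated correlation). Their array means overlapped those of DMSO (exact permutation p = 0.2). Their mean per array did not rise with both drugs, at -0.06 in WT EtopoTopo (exact permutation p = 0.5) and -0.25 in KO EtopoTopo (exact permutation p = 0.1). The p53 targets Cdkn1a and Bax were asked for but not measured, so the list does not cover them. Thymocyte genes fell (median -0.50, camera adjusted p = 6.76e-05, and 0.328 with an estimated correlation), with Thy1 at -0.79 ± 0.16 and with the high value of WT DMSO 1 among the controls. Macrophage and dendritic cell genes fell too (median -0.27, 1 of 19, 3 adjusted over the list alone, camera adjusted p = 0.00367, and 0.328 with an estimated correlation). In total 164 genes rose and 272 fell, and 55 changed at least 2-fold. The count of 436 fell to 219 without WT DMSO 1, 213 without WT DMSO 3, 103 without WT Topo 1, 243 without WT Topo 2 and 208 without WT Topo 3.

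Both drugs together changed more genes in WT MECs than either alone against DMSO, 711 higher and 1438 lower (n = 3 per group). Bitter taste receptors led the genes that rose, with Tas2r115 at 2.30 ± 0.35 (limma adjusted p = 0.000241) and Tas2r108 at 1.82 ± 0.23 (adjusted p = 5.55e-05). Of 13 tuft-like genes 10 rose (11 adjusted over the list alone), with Sh2d6 at 1.66 ± 0.21 and the phospholipase Plcb2 at 1.38 ± 0.24. The median was 1.03 (camera adjusted p = 1.9e-14, and 0.134 with an estimated correlation), and arrays of both groups did not overlap (exact permutation p = 0.1). Of 29 mitosis genes 24 fell (28 adjusted over the list alone), with topoisomerase II alpha, Top2a, at -1.29 ± 0.27 (adjusted p = 0.00359) and the cell cycle kinase Cdk1 at -1.15 ± 0.17. The median was -0.77 (camera adjusted p = 1.35e-18, and 0.134 with an estimated correlation; exact permutation p = 0.1 for array means). DNA replication genes fell with them (median -0.26, 5 of 28 members, 6 adjusted over the list alone, camera adjusted p = 0.000142, and 0.292 with an estimated correlation), including the ribonucleotide reductase subunit Rrm2 (-0.87 ± 0.21).

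Cyp1a2 fell by 2.00 ± 0.18 in WT EtopoTopo (limma adjusted p = 2.53e-06), the fibrinogen gene Fgg by 1.81 ± 0.16 (adjusted p = 2.53e-06) and albumin, Alb, by 1.37 ± 0.20. Of 33 Aire-dependent antigens 14 fell and 0 rose (16 and 2 adjusted over the list alone, median -0.41, camera adjusted p = 2.41e-08, and 0.142 with an estimated correlation). The fall was not confined to them. Aire-independent antigens fell (median -0.21, 3 of 12, 6 adjusted over the list alone, camera adjusted p = 0.0389, and 0.292 with an estimated correlation), as did cTEC genes (median -0.21, 2 of 13, 3 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.0219, and 0.278 with an estimated correlation). Mature MEC genes fell (median -0.15, 6 of 23 members, 6 adjusted over the list alone, camera adjusted p = 0.000964, and 0.363 with an estimated correlation), with Cd83 at -1.01 ± 0.15 and Cd40 at -0.84 ± 0.12. Thymocyte genes (median -0.57, 2 of 17 members fell, camera adjusted p = 0.000642, and 0.373 with an estimated correlation) and macrophage and dendritic cell genes (median -0.38, 4 of 19 fell, camera adjusted p = 0.00796, and 0.308 with an estimated correlation) fell as well, with WT DMSO 1 high in the thymocyte list. Among all genes called, 66.9% were lower, and after quantile normalization of the arrays 1380 were higher and 1580 lower. The count of 2149 was 1110 without WT DMSO 1, 1138 without WT EtopoTopo 2, 1347 without WT EtopoTopo 3, 462 with age as a covariate and 251 without both arrays whose labels conflict.

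The 640 Aire-induced genes shifted down in WT arrays with each drug and up in KO arrays with both drugs. Their mean shift was -0.18 in WT Etopo (fry adjusted p = 0.037), -0.37 in WT Topo (fry adjusted p = 0.000601) and -0.59 in WT EtopoTopo (fry adjusted p = 9.04e-06), with 76.4%, 82.5% and 87.2% of the genes below 0. By camera with an estimated correlation the Topo and EtopoTopo shifts passed (adjusted p = 0.00407 for each) and the Etopo shift did not (adjusted p = 0.0896). In WT Topo 153 of them fell and 17 rose, and in WT EtopoTopo 374 fell and 16 rose. In the KO the shift was 0.10 with Etopo (fry adjusted p = 0.225), 0.15 with Topo (fry adjusted p = 0.0932) and 0.34 with EtopoTopo (fry adjusted p = 0.00254), where 129 rose and 0 fell, and camera with an estimated correlation gave adjusted p = 0.107 for the last. After quantile normalization the KO shifts were 0.06 with Etopo, 0.10 with Topo and 0.16 with EtopoTopo. The Aire-induced list was low in KO DMSO (mean 6.90). Olfactory and vomeronasal receptors, mostly silent genes, rose in KO EtopoTopo by a median of 0.49, and by 0.16 after quantile normalization. A rise of low values on these arrays thus cannot be told apart from a rise of the list. The list was chosen on the DMSO arrays used here as controls, so its direction is not independent evidence. Simulated unchanged groups moved by -0.0305 for WT Topo and -0.0303 for WT EtopoTopo on average. With a list chosen from the arrays of the other drugs, the shift was 0.04 in WT Etopo (fry adjusted p = 0.532), -0.09 in WT Topo (fry adjusted p = 0.27) and -0.41 in WT EtopoTopo (fry adjusted p = 0.000162), and in the KO 0.18 with Topo (fry adjusted p = 0.0194) and 0.28 with EtopoTopo (fry adjusted p = 0.00732, camera adjusted p = 0.177 with an estimated correlation). The list from the other drugs' arrays requires a 2-fold difference on treated arrays, so genes that the drugs lower in WT can drop out of it. In WT Topo 43 of its 381 genes rose and 67 fell, against 17 and 153 of the 640. It is thus not a neutral check of the shift, and how far this explains the difference between the lists was not tested.

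Means of the Aire-induced list per array were 8.54 to 8.68 in WT DMSO, 8.32 to 8.54 in WT Etopo (exact permutation p = 0.2 without pairs), 8.19 to 8.32 in WT Topo (exact permutation p = 0.1) and 7.91 to 8.07 in WT EtopoTopo (exact permutation p = 0.1). In the KO they were 6.83 to 6.97 under DMSO, 6.97 to 7.17 under Topo, and 7.38 in KO EtopoTopo 1 against 7.09 in KO EtopoTopo 2. Replicate numbers pair WT Etopo with WT DMSO, and the 3 differences within pairs were -0.14, -0.17 and -0.22 (exact sign-flip p = 0.25, the smallest that 3 pairs allow). For KO Topo and KO DMSO, whose pairing by number is in doubt, the differences were 0.34, 0.0004 and 0.11 (exact sign-flip p = 0.25). The call of the WT Etopo shift was lost without WT DMSO 1 (-0.14), WT DMSO 2 (-0.17), WT Etopo 2 (-0.18) or WT Etopo 3 (-0.12). That of KO EtopoTopo was lost without KO EtopoTopo 1 (0.19). The 136 Aire-repressed genes shifted by -0.21 in WT EtopoTopo (fry adjusted p = 0.0495) and -0.41 in KO EtopoTopo (fry adjusted p = 0.00389), both with camera adjusted p = 0.262 at an estimated correlation, with values of -0.20 in KO Topo (fry adjusted p = 0.0747) and -0.08 in WT Topo (fry adjusted p = 0.379).

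**Figure D1:**
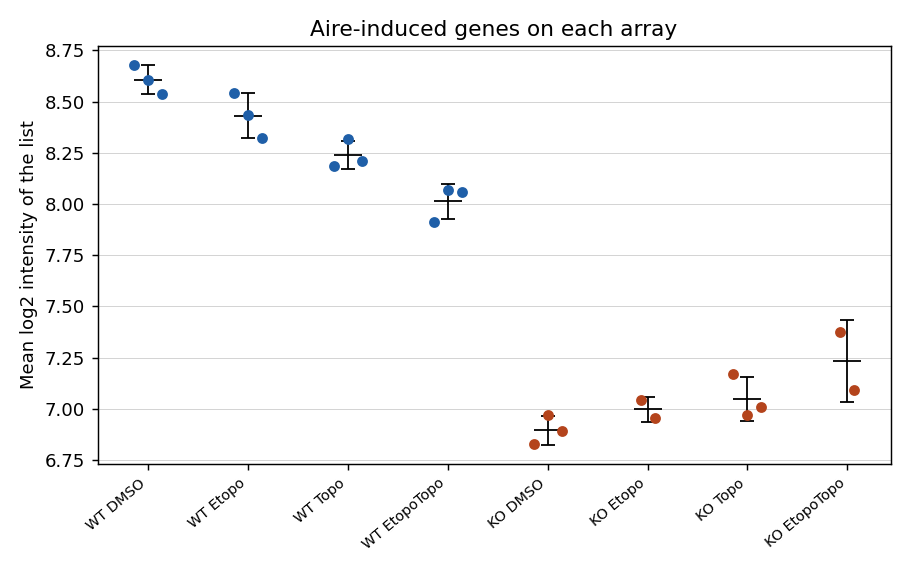
Mean log2 intensity of the 640 Aire-induced genes (vertical axis) by genotype and treatment (horizontal axis). Each point is 1 array, and bars give the group mean ± SD (8.61 in WT DMSO, 8.24 in WT Topo, 8.01 in WT EtopoTopo and 6.90 in KO DMSO).

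Etopo in KO MECs lowered genes of cell division as a group (2 Etopo and 3 DMSO arrays). The mitosis list fell (median -0.75, camera adjusted p = 8.65e-49, and 0.00454 with an estimated correlation), with 27 of 29 members lower when adjusted over the list alone. DNA replication genes fell too (median -0.39, 13 of 28 adjusted over the list alone, camera adjusted p = 3.6e-25, and 0.00454 with an estimated correlation). The mitotic kinesin Kif11 stood at -1.31 ± 0.27 (limma adjusted p = 0.209 over all genes), the proliferation marker Mki67 at -1.17 ± 0.24 (adjusted p = 0.209) and Rrm2 at -1.14 ± 0.23 (adjusted p = 0.209). Thymocyte genes fell (median -0.66, camera adjusted p = 5.5e-11, and 0.259 with an estimated correlation), with KO DMSO 1 at 8.79 among the controls. The tuft-like list rose (median 0.27, camera adjusted p = 0.00106, and 0.403 with an estimated correlation; exact permutation p = 0.3 for array means). Over all genes, limma called 0, and 2 without KO DMSO 2. At an unadjusted p under 0.05 lay 707 genes, fewer than the 988 expected with no change.

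Topo in KO MECs lowered cell division genes and raised tuft cell genes, with single taste genes (n = 3 per group). Of 29 mitosis genes 17 fell (27 adjusted over the list alone), among them Kif11 (-1.20 ± 0.24, limma adjusted p = 0.0169), Mki67 (-1.20 ± 0.22, adjusted p = 0.0131) and Top2a (-1.11 ± 0.27, adjusted p = 0.0475). The median was -0.79 (camera adjusted p = 1.94e-35, and 0.0193 with an estimated correlation; exact permutation p = 0.1 for array means). DNA replication genes fell (median -0.37, 6 of 28 members, 17 adjusted over the list alone, camera adjusted p = 8.84e-18, and 0.0193 with an estimated correlation), led by Rrm2 (-1.28 ± 0.21, adjusted p = 0.00894). The club cell secretoglobin Scgb1a1 rose by 1.56 ± 0.33 (adjusted p = 0.0241), Tas2r108 by 1.23 ± 0.23 (adjusted p = 0.0134) and Gnat3 by 1.05 ± 0.22 (adjusted p = 0.0261). Tuft-like genes rose (median 0.57, 1 of 13, 9 adjusted over the list alone, camera adjusted p = 8.2e-12, and 0.0748 with an estimated correlation; exact permutation p = 0.1 for array means).

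Cornified MEC genes rose in KO Topo (median 0.44, 0 of 17, 6 adjusted over the list alone, camera adjusted p = 2.73e-08, and 0.0748 with an estimated correlation). Thymocyte genes fell (median -0.69, 2 of 17, 3 adjusted over the list alone, camera adjusted p = 1.41e-07, and 0.346 with an estimated correlation), Cd4 by 1.03 ± 0.24, with the high value of KO DMSO 1 among the controls. Macrophage and dendritic cell genes rose (median 0.16, 0 of 19, 1 adjusted over the list alone, camera adjusted p = 0.0369, and 0.533 with an estimated correlation), and KO Topo 1 had their highest mean per array at 8.79. Without KO Topo 1 their median reversed to -0.03. The difference between genotypes in the Topo effect on this list was 0.38 in the median (camera adjusted p = 1.84e-06, and 0.147 with an estimated correlation). In total 50 genes rose and 154 fell (75.5% lower), and after quantile normalization 60 rose and 101 fell. The count of 204 was 1 without KO DMSO 3, 60 without KO Topo 1, 118 without KO Topo 3 and 0 with only the groups compared in the fit.

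Immediate early, chromatin and division genes were lower in KO MECs with both drugs together than with DMSO (2 EtopoTopo and 3 DMSO arrays). The EtopoTopo arrays came from mice of 4 weeks and the DMSO arrays from mice of 6 weeks, so age and treatment cannot be separated here. The AP-1 genes Fos (-1.73 ± 0.55, limma adjusted p = 0.0325) and Jun (-1.65 ± 0.26, adjusted p = 0.00175) and the basal keratin Krt17 (-1.76 ± 0.37, adjusted p = 0.00585) fell. Without KO EtopoTopo 1 these 3 calls were lost, at -1.33 for Fos (adjusted p = 0.438), -1.34 for Jun (adjusted p = 0.0673) and -0.55 for Krt17 (adjusted p = 0.189). Of 25 immediate early and stress genes 11 fell (11 adjusted over the list alone, median -0.78, camera adjusted p = 3.83e-06, and 0.326 with an estimated correlation). The mean of that list per array was 10.63 in KO DMSO 1 and 9.91 in the other two controls, against 9.13 and 9.59 under EtopoTopo. Of 29 mitosis genes 20 fell (25 adjusted over the list alone, median -0.75, camera adjusted p = 2.7e-12, and 0.315 with an estimated correlation), with Top2a at -1.64 ± 0.30 and Cdk1 at -1.31 ± 0.19. Of 32 Aire partners and topoisomerases 13 fell and 0 rose (16 and 1 adjusted over the list alone, median -0.36, camera adjusted p = 3.84e-06, and 0.315 with an estimated correlation), and of 23 mature MEC genes 11 fell (12 adjusted over the list alone, median -0.43, camera adjusted p = 2.65e-06, and 0.315 with an estimated correlation). Core histones fell (median -0.56, 7 of 15, 8 adjusted over the list alone, camera adjusted p = 0.000726, and 0.326 with an estimated correlation). Much of these falls lay in KO EtopoTopo 1, with array means of 10.90 against 11.58 in KO EtopoTopo 2 for mature MEC genes, 9.29 against 9.65 for Aire partners and 8.39 against 8.77 for core histones. Without it the medians were -0.13, -0.20 and -0.41, that of immediate early and stress genes was -0.44 and that of mitosis genes -0.69.

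Scgb1a1 (2.49 ± 0.37, limma adjusted p = 0.000894) and the hepcidin genes Hamp2 (1.73 ± 0.25, adjusted p = 0.000826) and Hamp (1.64 ± 0.27, adjusted p = 0.0018) rose in KO EtopoTopo. Of 33 Aire-dependent antigens 7 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.25, camera adjusted p = 0.00934, and 0.407 with an estimated correlation), with Csn1s2a at 1.33 ± 0.23. Without KO EtopoTopo 1 the antigen median was 0.08 (camera adjusted p = 0.152), and the calls of Scgb1a1 (1.91, adjusted p = 0.0515) and Hamp (1.31, adjusted p = 0.0684) were lost. The tuft-like list rose (median 0.33, 2 of 13, camera adjusted p = 0.035, and 0.522 with an estimated correlation), though its mean was 9.08 in KO EtopoTopo 1 and 9.99 in KO EtopoTopo 2 (exact permutation p = 0.4). Its median change was 0.82 without KO EtopoTopo 1 and -0.08 without KO EtopoTopo 2, so 1 array turns its direction. In total 2194 genes rose and 2319 fell. The count of 4513 was 68 without KO EtopoTopo 1, the array with the narrowest range of values, 9170 without KO EtopoTopo 2, 2902 without KO DMSO 1, 2958 without KO DMSO 2 and 1850 without KO DMSO 3. It was 2857 after quantile normalization, 5 with age as a covariate and 0 with only the groups compared in the fit.

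**Figure D2:**
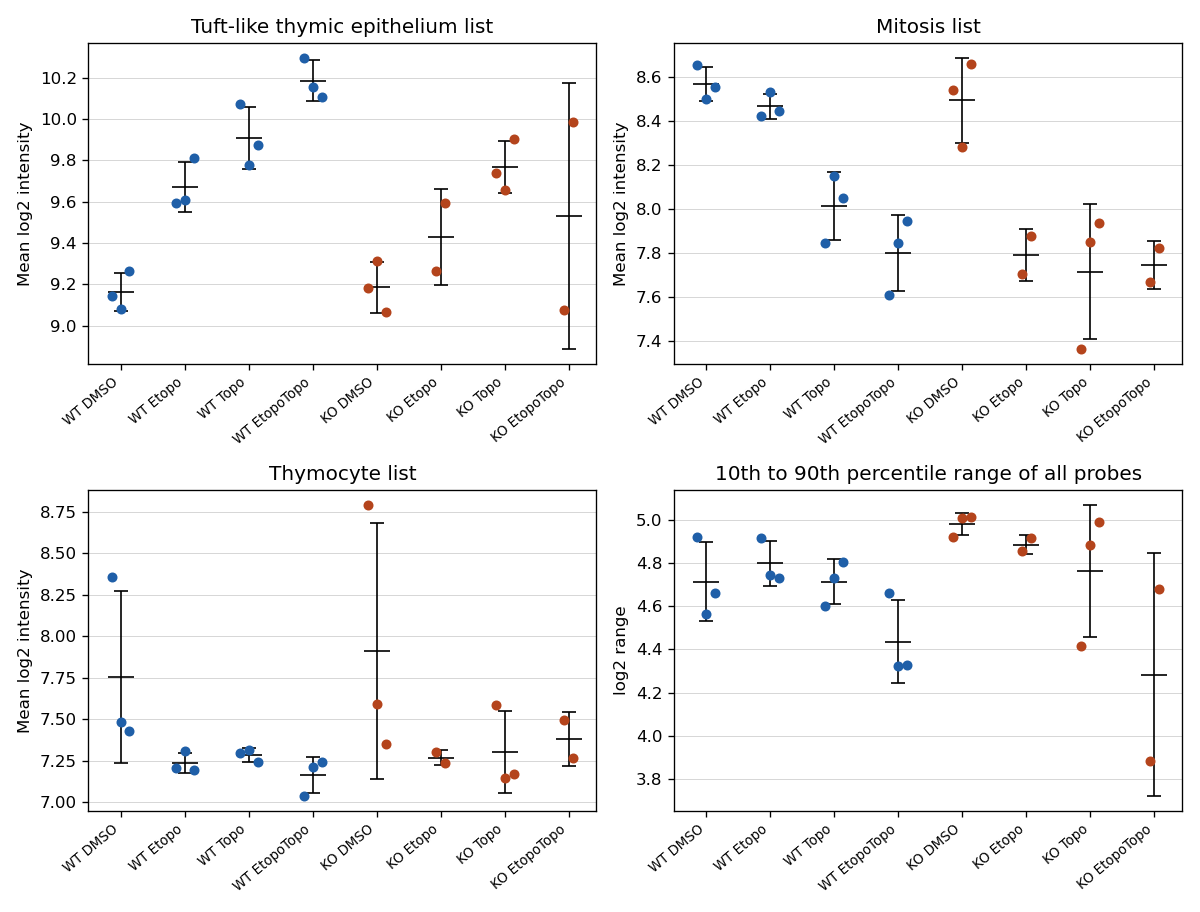
Mean log2 intensity of the tuft-like, mitosis and thymocyte lists and the range between the 10th and 90th percentile of all probes (vertical axes) by group (horizontal axes). Points are arrays, with thymocyte means of 8.36 in WT DMSO 1 and 8.79 in KO DMSO 1 and a range of 3.89 in KO EtopoTopo 1.

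The effect of Topo differed between genotypes for 15 genes, all higher in the KO relative to WT and all among the 640 Aire-induced genes. Those 640 were chosen on DMSO arrays that also enter this difference, so its direction is not independent evidence. The 640 were also low already in KO DMSO (mean 6.90, against 8.61 in WT DMSO), so a drug had less room to lower them there. The 15 include Cyp1a2 (1.42 ± 0.25, limma adjusted p = 0.0267), the resistin-like gene Retnla (1.46 ± 0.26, adjusted p = 0.0276) and Nid1 (1.34 ± 0.18, adjusted p = 0.007). Of 33 Aire-dependent antigens 1 was called (7 adjusted over the list alone), with a median difference of 0.41 (camera adjusted p = 1.43e-13, and 0.0845 with an estimated correlation). DNA replication genes had a median difference of -0.26 (camera adjusted p = 2.36e-08, and 0.147 with an estimated correlation), and the tuft-like list had -0.27 without passing (camera adjusted p = 0.0876). The Aire-induced list differed by 0.52 (fry adjusted p = 0.000601), and by 0.27 (fry adjusted p = 0.0194) for the list from the other drugs' arrays. The count of 15 was 3 without WT DMSO 1, 4 without WT DMSO 3, 1 without KO DMSO 1, 3 without KO DMSO 3, 4 without WT Topo 1, 0 without WT Topo 3 and 5 without KO Topo 3.

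For both drugs together the genotypes differed at 486 genes, 465 higher and 21 lower in the KO relative to WT. Pth (2.89 ± 0.37, limma adjusted p = 0.000168), the carbonic anhydrase Car1 (2.74 ± 0.37, adjusted p = 0.000371) and Amtn (2.67 ± 0.34, adjusted p = 0.000159) differed upward. In KO DMSO their means were already low, at 4.83, 6.17 and 5.95, against 9.02, 10.59 and 10.18 in WT DMSO. A drug thus had less room to lower them in the KO. Jun (-1.39 ± 0.35, adjusted p = 0.0389) and the basal keratin Krt5 (-1.28 ± 0.34, adjusted p = 0.0466) differed downward, calls lost without KO EtopoTopo 1 (-1.08, adjusted p = 0.408, and -0.97, adjusted p = 0.467). Of 33 Aire-dependent antigens 12 were higher (19 adjusted over the list alone), with a median of 0.60 (camera adjusted p = 6.54e-15, and 0.0607 with an estimated correlation). The tuft-like list was lower by 0.70 in the median (0 of 13, 5 adjusted over the list alone, camera adjusted p = 7.23e-07, and 0.284 with an estimated correlation). Much of this lay in KO EtopoTopo 1, without which the median difference was -0.28 (camera adjusted p = 0.0123, and 0.59 with an estimated correlation). The Aire-induced list differed by 0.93 (fry adjusted p = 8.84e-06), with 303 members higher and 0 lower, and by 0.69 (fry adjusted p = 8.7e-05) for the list from the other drugs' arrays. The count of 486 was 309 without WT DMSO 2, 290 without KO DMSO 1, 252 without WT EtopoTopo 1, 123 without KO EtopoTopo 1 and 4178 without KO EtopoTopo 2. It was 92 without both WT EtopoTopo arrays of conflicting label, 190 with only the groups compared and 263 after quantile normalization.

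For Etopo alone the cell division genes differed between genotypes as lists, mitosis by -0.61 (0 of 29, 9 lower adjusted over the list alone, camera adjusted p = 4.37e-22, and 0.0805 with an estimated correlation) and DNA replication by -0.38 (camera adjusted p = 1.15e-15, and 0.0621 with an estimated correlation). The Aire-induced list differed by 0.28 (fry adjusted p = 0.0339, and camera adjusted p = 0.0571 with an estimated correlation), and by 0.0077 (fry adjusted p = 0.937) for the list from the other drugs' arrays. Over all genes limma called 0, and 1 without WT DMSO 3. At an unadjusted p under 0.05 lay 907 genes, fewer than the 988 expected with no change.

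Against each other, Topo and Etopo differed in WT MECs in the mitosis list, lower with Topo (median -0.48, 0 of 29, 15 adjusted over the list alone, camera adjusted p = 3.49e-30, and 0.0564 with an estimated correlation). Aire-dependent antigens were lower as well (median -0.22, camera adjusted p = 3.12e-07, and 0.237 with an estimated correlation). The only gene called was Ppp1r17 (-1.11 ± 0.17, limma adjusted p = 0.0439). The count was 0 without WT Etopo 1, WT Etopo 2 or any of the 3 WT Topo arrays, and 2 without WT Etopo 3.

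Adding Etopo to Topo in WT MECs raised 27 genes and lowered 48, with age differing between the groups. Sh2d6 of tuft cells rose by 1.03 ± 0.21 (limma adjusted p = 0.0448) and Csta2 by 1.27 ± 0.16 (adjusted p = 0.00157), while the tryptophan-degrading enzyme Tdo2 fell by 1.43 ± 0.27 (adjusted p = 0.0416) and Pth by 1.22 ± 0.25 (adjusted p = 0.0431). The tuft-like list rose (median 0.22, 1 of 13, camera adjusted p = 0.00287, and 0.574 with an estimated correlation), and antigens fell (median -0.26, 2 of 33, 6 adjusted over the list alone, camera adjusted p = 0.00287, and 0.574 with an estimated correlation). After quantile normalization 134 genes were higher and 117 lower. The count of 75 was 7 without WT Topo 1, 2 without WT Topo 2 or WT Topo 3, 3 without WT EtopoTopo 2, 4 without WT EtopoTopo 3 and 0 with age as a covariate. It was 1 without both arrays of conflicting label, 14 with the replicate number as a block, 4 with sex as a covariate and 1500 with only the groups compared.

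Genes called for loss of Aire and for a drug overlapped in like and in opposite directions. For WT Topo 190 genes were lower in both (32.5 under independence), 6 higher in both (12.1), 61 lower in KO and higher with the drug (19.6) and 23 the reverse (20.1). For WT EtopoTopo the counts were 565 (172), 35 (52.6), 109 (85.1) and 201 (106). The changes compared share the WT DMSO arrays, so independence is not what unchanged groups would give. The simulated groups, KO included, were all drawn from the WT DMSO means and so held neither a drug nor an Aire effect. Their correlation over genes was 0.501 for WT Topo, against 0.235 observed, and their covariance was 0.0136, below the 0.0251 observed. The observed correlation also carries the spread of the Aire effect, so simulated and observed correlations cannot be compared. For WT EtopoTopo the simulated correlation was 0.5 and the observed one 0.188, and the simulated covariance was 0.0136 and the observed one 0.0292.

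Across 14900 expressed genes of known length (GRCm38.p6), Spearman correlations of the change with length were -0.219 for KO Etopo, -0.142 for KO Topo and -0.116 for KO EtopoTopo, and 0.021, -0.0645 and 0.0384 for the same drugs in WT. The KO comparisons share the KO DMSO arrays, and without KO DMSO 1, the array rich in thymocyte transcripts, the KO correlations were -0.0197, 0.0185 and -0.0324. Single DMSO arrays differed as much from the others of their genotype, with correlations of 0.338 for KO DMSO 1 and -0.321 for WT DMSO 2, so no relation of the drug effects to length is reported.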

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

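The tests of the shift on separate DMSO arrays, of Aire RNA and of thymocyte RNA were chosen only after the results were seen, while the list from the other drugs' arrays and the regrouping of arrays were chosen before.

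Differences between the genotypes in the drug effects stood out. The Topo effect differed at 15 genes and the EtopoTopo effect at 486. All 15 and 303 of the 486 belong to the Aire-induced list, which was chosen on DMSO arrays that enter these differences. Its low mean in KO DMSO (6.90) also left less room for a fall there. That list differed by 0.28 (0.27657) for Etopo, 0.52 (0.51895) for Topo and 0.93 (0.93019) for EtopoTopo. The Etopo difference did not pass at an estimated correlation (camera adjusted p = 0.0571) and was 0.0077 on the list from the other drugs' arrays (fry adjusted p = 0.937), against 0.27 and 0.69 for the other two. For EtopoTopo the mean of Aire-dependent antigens differed by 0.84 (0.84372), that of B cell genes by 0.43 (0.43274) and that of macrophage and dendritic cell genes by 0.49 (0.48804), with camera adjusted p = 0.0607, 0.0694 and 0.284 at an estimated correlation. Without KO EtopoTopo 1 these means were 0.68, 0.34 and 0.54, and the B cell median went from 0.36 to 0.23.

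Aire-induced genes were lower in WT Topo and WT EtopoTopo. A hypothesis is that topoisomerase inhibition weakens induction by Aire, and it could be tested by Aire occupancy and nascent RNA in treated WT cells. Selection on shared WT DMSO arrays is excluded as the whole cause. On DMSO arrays not used to choose the list the shift was -0.33 for Topo and -0.55 for EtopoTopo. Simulated unchanged groups reached -0.0468 and -0.0495 at the lowest. The simulation drew each gene independently (SD of the shift 0.0067 and 0.0066), while the list mean varied between WT DMSO arrays with an SD of 0.071. Those lowest values are thus too narrow a bound and do not add to the exclusion. The list from the other drugs' arrays gave -0.09 and -0.41, with 284 of its 381 and 373 of its 463 genes shared, so for Topo the size of the shift stays open. Less Aire RNA cannot be told apart from a weaker effect of Aire, since Aire changed by -0.53 (-0.52588) with Topo and -0.63 (-0.63028) with EtopoTopo. A smaller share of mature MECs among the sorted cells was not tested and stays open as well. The mean of mature MEC genes per array changed by -0.16 with Topo and -0.32 with EtopoTopo (exact permutation p = 0.1 for each). Thymocyte RNA in WT DMSO 1 is excluded, as the shift without the DMSO arrays richest in it was -0.33 (-0.3317) and -0.56. For EtopoTopo age stays open, since all its WT arrays came from mice of 4 weeks and only WT DMSO 3 of the controls did. The arrays from 4 weeks had the lowest list mean in WT DMSO (8.54) and in WT Etopo (8.32). Against WT DMSO 3 alone the EtopoTopo shift was -0.48, on a list chosen without that array.

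For the Topo interaction, 3 of 100 groupings of treatment within genotype, the real one counted among them, called at least the 15 genes of the real grouping, a share under 0.05. The highest other grouping called 173. Regrouping within a genotype can turn Topo effects shared by both genotypes into an apparent interaction. These groupings thus do not show what would be called without an interaction, and the share does not decide whether the 15 arose by chance.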

How the results depend on the processing

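The tests without both DMSO arrays rich in thymocyte RNA, without both KO arrays of narrow range, with a thymocyte covariate and on separate DMSO arrays were chosen only after the results were seen. Arrays give relative signal, no detection p was used, and fold changes at low signal are compressed. Except where said otherwise the cause of a difference was not tested. Values below are counts of genes called, or mean shifts of the Aire-induced list where named.

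With the replicate number as a block in place of no pairing, WT Topo against Etopo called 0 and WT EtopoTopo against Topo 14. Without low genes the Topo interaction called 25, and with trend and robust variances 34. After quantile normalization the counts were 3 for WT Etopo, 2857 for KO EtopoTopo, 263 for the EtopoTopo interaction and 251 for WT EtopoTopo against Topo. With array weights, which had not converged, they were 8412 for KO against WT, 1345 for WT Etopo, 4553 for WT Topo, 6000 for WT EtopoTopo, 246 for KO Etopo, 1368 for KO Topo and 0 for KO EtopoTopo. With these weights the interactions called 624 (Etopo), 1168 (Topo) and 74 (EtopoTopo), WT Topo against Etopo 12 and WT EtopoTopo against Topo 3384.

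With age as a covariate, WT EtopoTopo called 462, KO EtopoTopo 5, the Etopo interaction 1 and WT EtopoTopo against Topo 0. Age varied within a group only in WT DMSO and WT Etopo, so those groups alone set the age term. With sex by label as a covariate, WT Topo against Etopo called 0 and WT EtopoTopo against Topo 4. The transcripts contradict the male labels, so this covariate does not measure sex. With only the groups compared, WT Etopo, KO Topo, KO EtopoTopo and WT Topo against Etopo called 0, the EtopoTopo interaction 190 and WT EtopoTopo against Topo 1500, and the list shift was -0.18 (-0.1753) in WT Etopo and 0.34 (0.3376) in KO EtopoTopo, neither of which passed. Without both WT EtopoTopo arrays of conflicting label, WT EtopoTopo called 251, its interaction 92 and WT EtopoTopo against Topo 1. That setting left a single array in the group, so its lost calls do not show a dependence on the labels. With a 2-fold minimum the counts were 776 for KO against WT, 55 for WT Topo, 259 for WT EtopoTopo, 25 for KO Topo, 333 for KO EtopoTopo, 286 for the EtopoTopo interaction and 20 for WT EtopoTopo against Topo. The list from the other drugs' arrays reversed the WT Etopo shift to 0.04 (0.04025) and gave -0.09 (-0.09473) in WT Topo and 0.18 (0.1754) in KO Topo.

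Without both DMSO arrays rich in thymocyte RNA the counts were 0 for WT Etopo, 230 for WT Topo, 1227 for WT EtopoTopo, 120 for KO Topo, 2 for the Topo interaction, 247 for the EtopoTopo interaction, 0 for WT Topo against Etopo and 142 for WT EtopoTopo against Topo, and the WT Etopo shift was -0.14. Without both KO arrays of narrow range they were 17 for WT Etopo, 884 for WT Topo, 4137 for WT EtopoTopo, 1 for KO Etopo, 129 for KO Topo, 267 for KO EtopoTopo, 1 for the Etopo interaction, 42 for the Topo interaction, 194 for the EtopoTopo interaction and 1062 for WT EtopoTopo against Topo. With a thymocyte covariate they were 2 for WT Etopo, 366 for KO Topo, 24 for the Topo interaction, 0 for WT Topo against Etopo and 165 for WT EtopoTopo against Topo, and the WT Etopo shift was -0.15 (-0.1499).

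Leaving out each array in turn gave 0 to 3 for WT Etopo, 103 to 348 for WT Topo, 1110 to 1944 for WT EtopoTopo, 0 to 2 for KO Etopo, 1 to 181 for KO Topo and 68 to 9170 for KO EtopoTopo. It gave 0 to 1 for the Etopo interaction, 0 to 19 for the Topo interaction, 123 to 4178 for the EtopoTopo interaction, 0 to 2 for WT Topo against Etopo and 2 to 84 for WT EtopoTopo against Topo. The list shift ran from -0.23 (-0.2298) to -0.12 (-0.1197) in WT Etopo and from 0.19 (0.1947) to 0.48 (0.4805) in KO EtopoTopo.

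No named gene reversed. Of 137 named results 49 were weaker with only the groups compared, 44 with age, 27 without narrow KO arrays and 8 after quantile normalization. Of 50 named results with the WT combination 28 were weaker without its arrays of conflicting label, and leaving out each array weakened 269 of 882. Some lists reversed. Mature MEC in WT Topo was 0.004974 without both DMSO arrays rich in thymocyte RNA (-0.1036 to 0.004974 leaving out each array), and immediate early genes in KO Etopo were 0.02177 (-0.4756 to 0.02177) and 0.2016 with the thymocyte covariate. Macrophage and dendritic cell genes in KO Topo were -0.03484 without narrow KO arrays (-0.03484 to 0.227). With the thymocyte covariate the thymocyte list reversed by construction, to 0.05596 in WT Topo, 0.04143 in WT EtopoTopo, 0.02332 in KO Topo and 0.04977 in KO EtopoTopo, and the NF-kB list in KO Etopo to 0.00628. Leaving out each array, p53 targets in WT Etopo ran from -0.02402 to 0.1159, core histones in KO Etopo from -0.2399 to 0.003166, and the tuft-like list in KO EtopoTopo from -0.08111 to 0.8237.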

Other observations

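The tests of receptor families, the array of narrow range, unequal distributions and other epithelial lists were chosen only after the results were seen, while the matched lists for tuft-like genes and the regrouping of arrays were chosen before.

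Bitter taste receptors, which taste cells and tuft cells use to sense compounds, were higher with both drugs in WT. Of 34 Tas2r genes 21 rose in WT EtopoTopo (median 0.64, camera p = 0.0212 with an estimated correlation), 5 in WT Topo (0.29, p = 0.083), 3 in KO Topo (0.37, p = 0.0576) and 14 in KO EtopoTopo (0.58, p = 0.13), and 0 fell. After quantile normalization these counts were 22, 5, 2 and 5 and the medians 0.57, 0.27, 0.30 and 0.23, so the KO EtopoTopo value moved most. Olfactory and vomeronasal receptors, mostly silent outside sensory epithelia, were also higher in KO EtopoTopo (500 of 1194 rose and 1 fell, median 0.49), yet after quantile normalization 125 rose and the median was 0.16. In WT EtopoTopo 126 rose and 1 fell (median 0.31), and after quantile normalization 131 rose and 4 fell (0.16). Their mean per array was highest in KO EtopoTopo 1 (5.99), the array of narrowest range.

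In KO EtopoTopo 4513 genes were called. The explanation by 1 array, that of narrow range, fits, with 68 calls without KO EtopoTopo 1 against 9170 without the other array. Each run leaves 1 array in the group, and the spread then comes from the other groups only and is the same in both runs. Unequal distributions left by the authors' normalization alone are excluded, with 2857 calls after quantile normalization. Age cannot be separated from treatment in this comparison, which had 5 calls with age as a covariate.

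Tuft-like genes were higher in WT Topo and WT EtopoTopo. Raised low values on arrays of narrow range are excluded, since the list median lay at percentile 100 of 10000 lists matched on mean expression in both, where the highest random medians were 0.35 and 0.25. Loss of the main cell type cannot be told, since the sort gate would remove most cTEC and immature MEC, so the excess of the tuft-like list over cornified, immature and cTEC genes, 0.67 (SD 0.23) in WT Topo and 1.09 (SD 0.14) in WT EtopoTopo, does not decide. A larger share of tuft-like cells, whether by gain of them or loss of other cells, or a response within cells may lie behind it, a hypothesis that counting tuft cells in treated thymus would test. The camera p with an estimated correlation stays above 0.05 (0.0753 and 0.134), and for EtopoTopo age stays open.

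The 6 arrays of a comparison allow 10 regroupings into 3 and 3, too few for a share under 0.05. At least as many genes as in the real grouping were called by 1 of 10, the real one itself, for KO against WT under DMSO, WT Topo, WT EtopoTopo, WT Topo against Etopo and WT EtopoTopo against Topo, where the highest other regrouping called 0. For KO Topo it was 1 of 10 (highest other 3) and for WT Etopo 4 of 10 (highest other 5), the real one counted.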
